A study of Mus musculus with 4 samples.

How the data were processed

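The deposited data are 1 matrix of whole-number UMI counts per sample, for 4 samples of CD8-positive T cells, with 32285 genes per matrix named by Ensembl identifier and symbol. Per the labels' protocols, B16F10 tumours from C57BL/6J mice were chopped and digested with Liberase and DNase, cleared of red cells and debris (Percoll), sorted for live CD45, CD3 and CD8 positive cells, and made into 10x Genomics 5-prime libraries with a receptor amplification kit. Per the file headers, the counts were made with Cell Ranger 6.0.1, whereas the submitters' processing notes list Cell Ranger 3.0.2, Seurat and the genome build mm10; the difference could not be settled, and the annotation release is not given in the sources used here. No normalization had been applied to the deposited counts, and barcodes had already been limited to called cells. Removal of doublets before deposit is not stated. Groups and replicate numbers come from the sample titles.

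Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, 38316 of 39473. Scrublet, as implemented in scanpy 1.11.5, was run within each sample and called 0 doublets at automatic thresholds; a caller that marks none of this many cells has not worked, so doublets remain. Cells with at least 2 UMIs of each of 2 or more Trbv segments, which include doublets, were 11.1 and 10.6% of the sgScr and 6.73 and 13.2% of the sgArid1a T cells, and their removal was tried as an alternative. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were taken without receptor and immunoglobulin segments, mitochondrial, ribosomal and sex-linked genes, and cells were clustered on 30 principal components and 15 neighbours with Leiden at resolution 0.8 (leidenalg 0.10.2, igraph 0.11.9, random seed 1, no batch integration). A cluster was named only where at least 3 of a fixed marker list were raised in it and its leading genes did not go against the name; names here are rebuilt from markers and end in "-like". Other clusters kept their number, counted apart in the 2 clusterings used. A cluster of 56 cells with MHC class II and B cell genes was left out, which gave 38260 T cells: 7636 and 7157 in sgScr, 10695 and 12772 in sgArid1a.

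UMI counts were summed per sample over all T cells, or within each class with at least 50 cells in every sample, and tested with edgeR 4.0.16 (TMM normalization, filterByExpr, glmQLFit and glmQLFTest, no covariate, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. The sums behind the main test held 35642152 and 32201336 UMIs in sgScr and 39285383 and 81450019 in sgArid1a. The difference of the group effect between naive/central memory-like cells and cluster 8, the classes with most cells, was an interaction term with the sample as a block. Gene lists (32, fixed before the data were examined, 525 of 528 symbols matched; the ribosomal list, drawn up by gene name, also holds S6 kinases) were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on voom values, with an estimated correlation and fry beside it. The form with an estimated correlation draws on the residual degrees of freedom of only 4 samples, so it had little power to call any list. Lists with at least 3 tested members were used. Cells per cluster and per Trbv segment were tested with edgeR with the sample's total as offset, beside the exact two-sided permutation test, whose smallest p with 2 against 2 samples is 0.333. Because the clusters' own genes differed between groups, shares come from a clustering without the 6975 genes called or in the interferon lists. The Trbv segment of a cell was the one with at least 2 UMIs and more than any other. Pairs of segments were compared between libraries with Fisher's exact test. For the common cluster mix, mean profiles of clusters with at least 20 cells in every sample (the clustering with all variable genes) were weighted by one mix, and ratios were taken with a pseudocount of 1 CPM, which understates the change of low genes. Intervals are Wilson intervals at 95%, and the limit behind a count of 0 is 3 counts.

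The genes named were set by a rule fixed before the data were examined: among called genes with a mean of at least 20 CPM whose groups did not overlap, the 8 largest rises and 8 largest falls (5 per class), without receptor segments, predicted genes and pseudogenes; the 3 members with the smallest p of each called list and of 6 lists in any case; and 10 genes always, Arid1a, Cd8a, Cd3e, Ifng, Gzmb, Pdcd1, Havcr2, Tcf7, Isg15 and Mki67. Other genes named beside a list or an interaction were chosen after their values were seen. Coordinates are from the GENCODE M21 annotation of GRCm38, the build also called mm10, joined by Ensembl identifier.

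The edgeR step was tested on simulated counts drawn from the real means and library sizes and from dispersions fitted to these 4 samples. By each fold 100 genes were changed, equally up and down. Percentages are of those that passed the filter on low counts. For all T cells (12670 genes) it recovered 71.0% of the genes changed by 1.5-fold and 90.0% of those changed by 2-fold, with 11 unchanged genes called. For naive/central memory-like cells (10705 genes) these were 72.4% and 83.0%, with 3 unchanged genes called, and for terminally exhausted-like cells (10039 genes) 53.5% and 86.9%, with 11. Many more genes differed in the data, and the replicates may be technical. The simulation thus does not test normalization under so broad a shift, nor the spread between animals. Alternatives were 35 fixed before the data were examined and 14 added afterwards: other size factors, DESeq2 1.42.0, voom, other filters on genes and cells, equal depth and cell numbers, other resolutions, the replicate number as a block, and each sample left out in turn. Nothing in the labels says that a replicate number marks a shared animal or day, so the main fits are unpaired. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9 were used.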

Results

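CD8-positive T cells sorted from B16F10 tumours were profiled by droplet single-cell RNA sequencing with 5-prime libraries. B16F10 is a transplantable mouse melanoma line that grows in C57BL/6J mice. The labels give 2 groups of 2 samples each, sgScr (a scrambled guide RNA, the control) and sgArid1a (a guide RNA against Arid1a, a DNA-binding subunit of the SWI/SNF chromatin remodelling complex). They do not say which cells carried the guide. The series title places the comparison in a study of ARID1A, R-loops and the STING route to type I interferon. The 4 matrices held 7859 and 7376 barcodes in sgScr and 11153 and 13085 in sgArid1a, with 35881501, 32484099, 39713825 and 81916795 UMIs in the same order. The median UMIs per barcode were 3701 and 3548.5 in sgScr and 2335 and 3963 in sgArid1a. After filtering, 38260 T cells with 188578890 UMIs remained. Nothing in the labels says that replicates came from separate animals, so the p-values below measure only the spread between these samples, which may be technical; within each group the libraries carried the same expanded receptor segments (see the receptor comparison at the end).

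Arid1a itself (ENSMUSG00000007880, chromosome 4, 133679008 to 133756769, GRCm38) was read at 85.2 and 93.6 CPM (UMIs per 1000000 UMIs) in the sgScr samples and at 74.2 and 72.6 CPM in the sgArid1a samples, summed over all T cells. The log2 fold change was -0.26 ± 0.06 (SE), with an edgeR adjusted p of 0.00425. A guide can disrupt a protein without removing its transcript, and the T cells need not be the edited cells, so this level neither proves nor rules out editing. Without sgScr replicate 2 the fall was 0.22 on the log2 scale with an adjusted p of 0.0955, so this call rested on that sample; over its alternatives the edgeR or DESeq2 adjusted p ranged from 0.000295 to 0.0955. The T cell genes were present in every sample. Cd3e, a chain of the T cell receptor complex, stood at 877 and 910 CPM in the group means (adjusted p = 0.322), and the coreceptor gene Cd8a rose from 537 to 680 CPM (log2 0.37 ± 0.06, adjusted p = 0.00033).

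The question of the main comparison was how the tumour T cells of the sgArid1a group differed from those of the control. In T cells of the sgArid1a group, 16 of 19 cytotoxic effector genes and 10 of 13 chemokines and cytokines were higher. Of 17 progenitor and memory genes, 15 were lower. Camera called these lists at its preset correlation and none of them with an estimated correlation (camera adjusted p from 0.264 to 0.349). Among called genes with a mean of at least 20 CPM, the steepest rise was in Gzmc (ENSMUSG00000079186, chromosome 14, 56231441 to 56234656), a granzyme of strongly activated killer cells, from 14.7 ± 5.64 to 126 ± 47.7 CPM (mean ± SD, n = 2), a log2 fold change of 3.11 ± 0.23. Gzmf, its neighbour in the granzyme cluster, rose by 2.66 ± 0.16 and Ccl1, a chemokine of activated T cells, by 2.27 ± 0.25. Xcl1, which attracts cross-presenting dendritic cells, rose from 119 to 452 CPM (log2 1.96 ± 0.08), and Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), the interferon of killer T cells, from 36.9 to 116 CPM (log2 1.67 ± 0.16). The steepest fall above that level was in Tsc22d3 (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), the glucocorticoid-induced leucine zipper, from 326 ± 4.41 to 89.9 ± 11.2 CPM, a log2 fold change of -1.83 ± 0.07.

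The other 3 of the 8 largest rises were Nrgn, a calmodulin-binding protein (log2 2.09 ± 0.06), Eno3, an enolase (1.76 ± 0.06), and Gldc, the glycine decarboxylase (1.66 ± 0.07). The other 7 of the 8 largest falls were Pik3ip1, an inhibitor of PI3-kinase (-1.60 ± 0.06), Usp28, a deubiquitinase (-1.56 ± 0.07), Dtx1, a ubiquitin ligase of the Notch pathway (-1.49 ± 0.08), Igfbp4, a growth factor binding protein of naive T cells (-1.47 ± 0.08), Il6ra, the interleukin-6 receptor (-1.45 ± 0.06), Plekho1 (-1.38 ± 0.08) and Klf3, a transcription factor of quiescent cells (-1.34 ± 0.06). The adjusted p of these 16 genes in edgeR ranged from 4.78e-10 for Nrgn to 5.45e-06 for Ccl1. In total 6958 of 12792 genes passed an adjusted p of 0.05, 3580 higher and 3378 lower in sgArid1a. Of these, 550 rose and 365 fell by at least 2-fold, and without cycling-like cells 421 rose and 190 fell by that much. Of all 12792 genes tested, 9740 (76.1%) had both sgArid1a samples on the same side of both sgScr samples, an arrangement that chance gives to 33.3% of genes; the share includes the technical spread named above. DESeq2 called 2946 higher and 2433 lower.

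**Figure D1:**
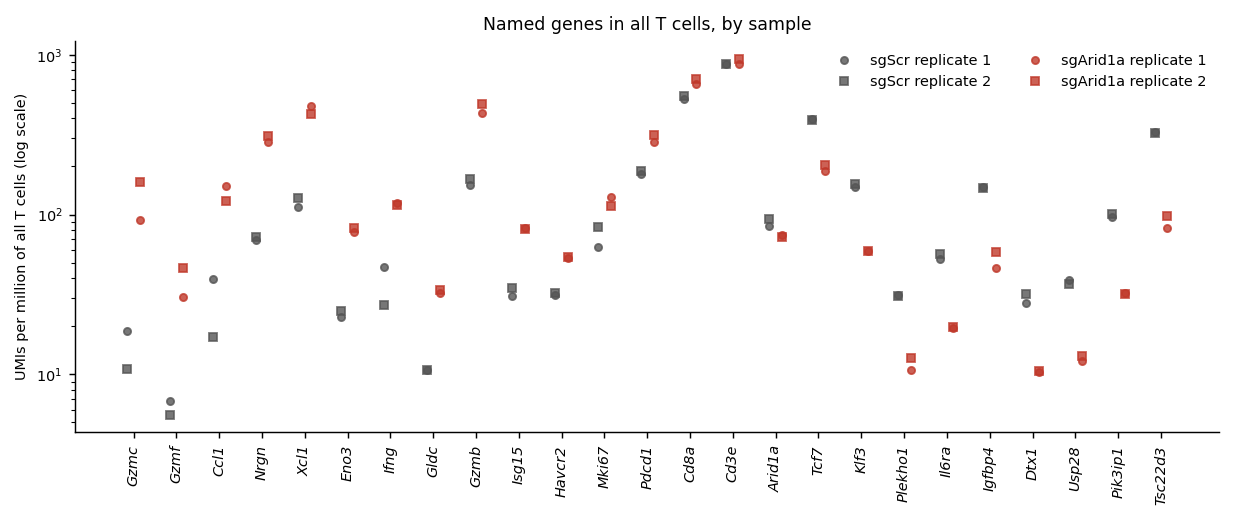
CPM (log axis) summed over all T cells of each sample, for the 8 largest rises, the 8 largest falls and the genes named in any case, ordered by fold change. Grey marks are sgScr and red marks sgArid1a, circles replicate 1 and squares replicate 2; Gzmc stands at 14.7 CPM in sgScr and 126 in sgArid1a on average, Tsc22d3 at 326 and 89.9, and Cd3e at 877 and 910.

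The fold changes were smaller at a common mix of clusters. These clusters were made with all genes, so they rest in part on the genes that changed, and holding them equal shrinks such changes by construction. When the mean profile of each cluster was weighted by the same cluster mix in all 4 samples, 13 of the 550 genes raised by at least 2-fold (2.36%) and 7 of the 365 lowered (1.92%) kept a change of that size. Among genes with a mean of at least 20 CPM these counts were 5 of 96 and 1 of 50, and the median log2 change of the 50 lowered genes went from -1.16 to -0.25. Gzmc kept a log2 ratio of 2.01 at the common mix, Xcl1 0.98, Isg15 0.78, Gzmb 0.49 and Tsc22d3 -0.73, while Tcf7 went to -0.13. The signs of Havcr2 (-0.39), Mki67 (-0.21), Pdcd1 (-0.08), Slc16a3 (-0.02) and Ifngr2 (0.01) were opposite to those over all T cells reported below, so these changes over all T cells are not shown to hold within states.

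Effector genes rose together. Of the 19 cytotoxic effector genes, 16 rose, 2 fell and 1 did not pass. Gzmb, the main granzyme of killer T cells (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), rose from 159 to 460 CPM (log2 1.56 ± 0.07), and Prf1, the pore-forming perforin, from 92.8 to 189 CPM (1.05 ± 0.07). Gzmk, a granzyme of less differentiated cells, fell by 0.40 ± 0.06, and Lamp1, a lysosomal membrane protein, fell by 0.30 ± 0.07. Of the 13 chemokines and cytokines, 10 rose, 1 fell and 2 did not pass. Csf1, a macrophage growth factor, rose by 1.85 ± 0.10 and Ccl3, an inflammatory chemokine, by 1.45 ± 0.10, while Il10, which dampens immune responses, fell by 1.44 ± 0.46 from under 1 CPM. Of the 18 inhibitory receptor and exhaustion genes, 14 rose and 2 fell. They included Pdcd1, the PD-1 checkpoint receptor (log2 0.73 ± 0.06), Havcr2, the TIM-3 receptor (0.78 ± 0.06), Rgs16, a regulator of G protein signalling (1.54 ± 0.06), Bhlhe40, an activation-induced repressor (0.93 ± 0.06), and Cd244a, the 2B4 receptor (1.27 ± 0.09). Camera at its preset correlation called these lists as raised. With an estimated correlation none was called, with adjusted p = 0.348 with an estimated correlation for the cytotoxic list, adjusted p = 0.349 with an estimated correlation for the chemokines and adjusted p = 0.264 with an estimated correlation for the inhibitory receptors. At the common cluster mix the median log2 ratios were 0.15 for the cytotoxic list, 0.44 for the chemokines and -0.11 for the inhibitory receptors. Over all T cells these medians were 0.87, 1.40 and 0.55. Granzymes C to G lie in a cluster of near-identical genes that may share reads, so their separate levels are uncertain.

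Genes of naive, memory and progenitor T cells moved the other way. Of 17 such genes, 15 fell and 2 rose. Lef1 and Tcf7, the transcription factors that keep T cells stem-like, fell by 1.24 ± 0.06 and 0.98 ± 0.06 on the log2 scale, Tcf7 from 393 to 196 CPM. Ccr7, the lymph node homing receptor, fell by 1.23 ± 0.06, and Bach2, a repressor of effector genes, fell by 1.16 ± 0.06. The 2 that rose were Id3, a memory-associated inhibitor of E proteins (0.41 ± 0.07), and Cd200, an immunoregulatory surface protein (1.19 ± 0.09). The list was called as lowered (adjusted p = 0.264 with an estimated correlation).

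Proliferation and energy genes were higher in sgArid1a. All 23 G2/M phase genes rose, among them Birc5, the survivin gene (log2 1.38 ± 0.06), Ube2c, a mitotic ubiquitin carrier (1.36 ± 0.06), Cdk1, the mitotic kinase (1.28 ± 0.06), and Mki67, the Ki-67 antigen, from 72.9 to 121 CPM (0.76 ± 0.10). Of the 25 S phase genes, 24 rose over all genes tested and 25 adjusted over the list alone, among them Dtl, a replication-coupled ubiquitin ligase subunit (1.40 ± 0.08), Gins2 of the replicative helicase (1.31 ± 0.08) and Tyms, the thymidylate synthase (1.26 ± 0.06). Both lists were called as raised (adjusted p = 0.264 with an estimated correlation for each). At the common cluster mix their median log2 ratios were -0.13 and 0.04, against 1.07 and 0.96 over all T cells. Of the 15 glycolysis genes, 11 rose and none fell, among them the lactate transporter Slc16a3 (0.90 ± 0.08), the isomerase Tpi1 (0.83 ± 0.06) and the mutase Pgam1 (0.82 ± 0.07), and 23 of the 24 oxidative phosphorylation genes rose, among them Cox5a of complex IV (0.75 ± 0.06), Atp5g1 of the ATP synthase (0.70 ± 0.07) and Ndufb7 of complex I (0.66 ± 0.07). Both were called (adjusted p = 0.404 with an estimated correlation and adjusted p = 0.360 with an estimated correlation). Their median log2 ratios at the common cluster mix were -0.02 and 0.10, against 0.60 and 0.51 over all T cells. The list named ribosomal protein genes was drawn up by gene name and also holds S6 kinases such as Rps6ka3 and the binding protein Rps19bp1. Of its 89 genes tested, 26 fell, such as Rps27 (-0.66 ± 0.10), and 7 rose (18 and 5 adjusted over the list alone), such as the ribosomal protein paralogs Rpl39l (1.42 ± 0.15) and Rps27l (139 to 273 CPM), and that list was called as lowered (adjusted p = 0.792 with an estimated correlation). Without the S6 kinases and Rps19bp1, a test added after seeing the data, 24 of 79 fell and 5 rose, and the camera adjusted p was 0.0126 (adjusted p = 0.792 with an estimated correlation). The call of the ribosomal protein genes was lost without sgScr replicate 1 (camera adjusted p = 0.268), without sgArid1a replicate 2 (0.147), without cycling-like cells (0.0872) and without Trbv13-1 and Trbv20 cells (0.163).

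Interferon-stimulated genes were higher in sgArid1a, while components of the pathway that induces and senses interferon were mostly lower. Of the 31 type I interferon-stimulated genes tested, 20 rose, 3 fell and 8 did not pass, with a median log2 fold change of 0.50. Isg15, a ubiquitin-like antiviral protein (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), rose from 32.8 ± 2.54 to 82.0 ± 1.30 CPM (1.35 ± 0.07), Rtp4, an antiviral transporter protein, by 0.90 ± 0.06 and Isg20, an antiviral exonuclease, by 0.76 ± 0.06. The 3 that fell were Ifi208, Ifi209 and Ifi213 of the nucleic acid-sensing PYHIN family, whose members may share reads. Of the 25 interferon-gamma response genes, 16 rose and 1 fell (17 and 1 adjusted over the list alone), among them the guanylate-binding protein Gbp6 (0.72 ± 0.07) and the immunoproteasome subunits Psmb9 (0.57 ± 0.06) and Psmb10 (0.51 ± 0.06). The gene that fell was Tgtp2, an interferon-induced GTPase whose reads may be shared with its copy Tgtp1. The type I list was called as raised (adjusted p = 0.311 with an estimated correlation), as was the interferon-gamma list (adjusted p = 0.289 with an estimated correlation). Of 13 STING and interferon signalling components, 7 fell, 1 rose and 5 did not pass. Ifngr2, a chain of the interferon-gamma receptor, fell by 1.45 ± 0.09, the kinase Ikbke fell by 0.83 ± 0.07 and the kinase Jak1 fell by 0.45 ± 0.07. The member that rose was Tmem173, which encodes STING (0.32 ± 0.06). That list was called as lowered (adjusted p = 0.349 with an estimated correlation), and the call was lost without cycling-like cells (camera adjusted p = 0.275) and without Trbv13-1 and Trbv20 cells (0.246). At the common cluster mix the median log2 ratio was 0.25 for each interferon list and 0.01 for the signalling components. MHC class I genes were not called as a list, with 2 of 8 lower and none higher.

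Genes of recent receptor stimulation and of cell stress were also higher. Of the 15 T cell receptor-induced early genes, 11 rose and 2 fell (12 and 2 adjusted over the list alone), including the interferon regulatory factor Irf8 (1.39 ± 0.07), the costimulatory receptor Tnfrsf9 (1.38 ± 0.07) and the orphan receptor Nr4a2 (1.22 ± 0.08); Cd69 and Zfp36l1 fell. Of the 19 heat shock and dissociation genes, which also respond to enzymatic digestion of tissue, 17 rose, 1 fell and 1 did not pass. They included the phosphatase Dusp1 (1.21 ± 0.08), the AP-1 factor Fos (0.86 ± 0.06) and the mitochondrial chaperonin Hspd1 (0.74 ± 0.06). At the common cluster mix the median log2 ratio of the receptor-induced list was 0.11, against 0.70 over all T cells. That of the heat shock list was 0.32, against 0.35. Both lists were called as raised (adjusted p = 0.264 with an estimated correlation for each).

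Markers of cells outside the gate moved in both directions. The 4 tested dendritic cell and MHC class II genes all rose, among them Cd74 (36.2 to 84.3 CPM, log2 1.25 ± 0.08), H2-Eb1 (1.17 ± 0.16) and H2-Ab1 (1.14 ± 0.12), and 3 of 4 natural killer markers rose, namely Fcer1g (8.17 to 29.7 CPM, 1.87 ± 0.14), Tyrobp (1.29 ± 0.15) and Klri2 (1.15 ± 0.23). Both lists were called (adjusted p = 0.404 with an estimated correlation and adjusted p = 0.440 with an estimated correlation), and that of the natural killer cell markers was lost without sgArid1a replicate 1 (camera adjusted p = 0.110). Activated mouse T cells can express several of these genes. Fcer1g was also a leading gene of cluster 10 in the clustering with all genes (264 CPM, against 11.4 in the rest). That cluster went from 2.77 to 7.28% of T cells. At the common cluster mix the median log2 ratio of the natural killer markers was 0.42, against 1.22 over all T cells. That of the dendritic cell and MHC class II genes was 0.18, against 1.16. Macrophage markers were not called as a list, with 5 of 9 higher, and their summed level was 47.3 CPM higher in sgArid1a, most of it from Cst3, a protease inhibitor of many cell types (113 to 158 CPM). The immunoglobulin gene Ighm fell from 142 to 113 CPM. The summed level of the type I interferon-stimulated list was 408 CPM higher.

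Of 32 lists, 29 could be tested, and camera called 13 as raised and 3 as lowered at its preset correlation. With an estimated correlation 0 lists passed, though 4 had an unadjusted p below the threshold, and fry called 15 of the 16. The S phase and heat shock lists had estimated correlations of 0.00538 and -0.0103, below the preset 0.01. Yet their unadjusted camera p went from 1.04e-15 to 0.0138 and from 8.36e-06 to 0.0401. That form draws on the residual degrees of freedom of only 4 samples. The missing calls there thus do not show that correlation between genes explains the lists, nor that the lists were unchanged. The other lists were not called: SWI/SNF subunits (5 of 16 higher, 5 lower), costimulatory receptors (4 of 9 higher, 1 lower), chemokine and cytokine receptors (11 of 18 higher, 5 lower), effector differentiation and killer receptors (9 of 14 higher, 4 lower), tissue residency genes (6 of 12 higher, 2 lower), hypoxia genes (4 of 11 higher, 4 lower), mitochondrially encoded genes (0 of 13 higher, 3 lower), B cell markers (0 of 3 higher, 3 lower), CD4 and regulatory T cell markers (2 of 6 higher, 2 lower), gamma-delta T cell markers (4 of 6 higher, 1 lower) and melanoma markers (0 of 4 higher, 1 lower). Neutrophil, erythroid and stromal markers had too few tested members.

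**Figure D2:**
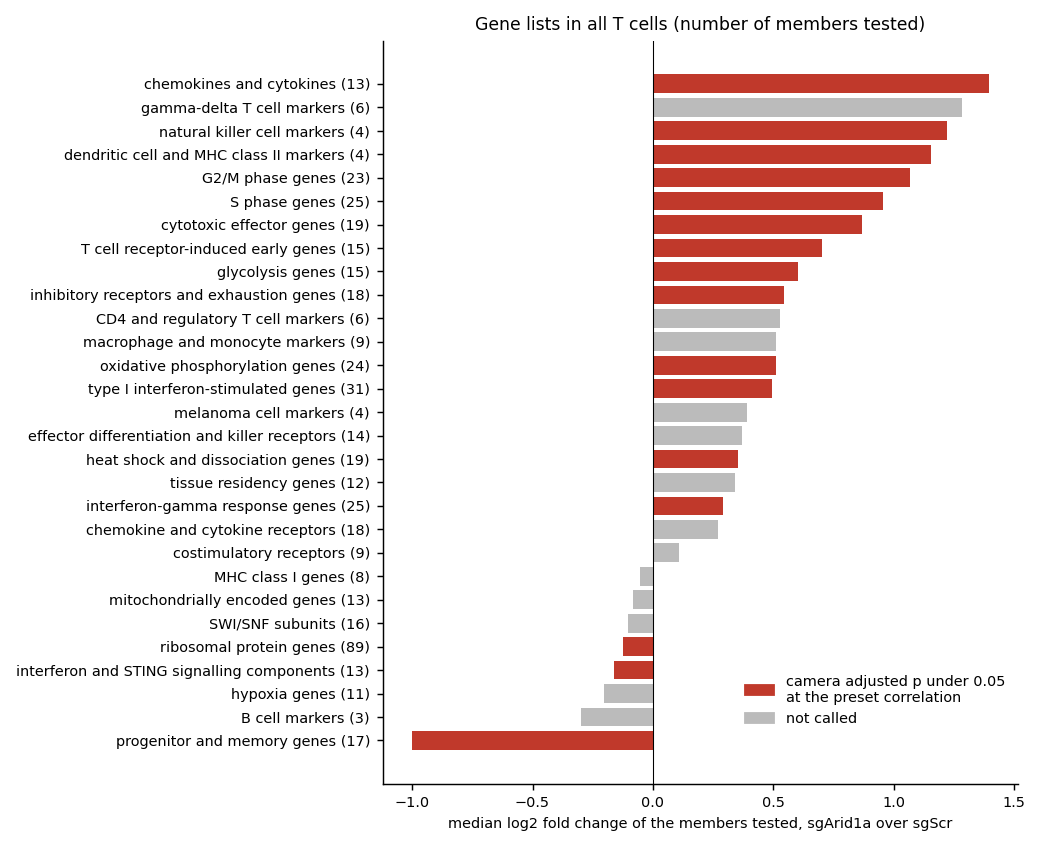
Median log2 fold change of the tested members of each gene list, sgArid1a over sgScr, summed over all T cells; red bars were called by camera at the preset correlation and grey bars were not, and none was called with an estimated correlation. Progenitor and memory genes have the lowest median and chemokines and cytokines the highest (1.40).

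Within cell classes the comparison asked what changed besides the mix of states. Clustering gave 12 classes and numbered clusters of T cells, of which 10 had at least 50 cells in every sample. In terminally exhausted-like cells, which express many checkpoint receptors, the granzymes Gzmd, Gzmc and Gzme rose by 3.45 ± 0.45, 2.47 ± 0.32 and 2.22 ± 0.37, Xcl1 by 2.12 ± 0.10 and the Fc receptor gamma chain Fcer1g by 1.96 ± 0.21. The killer cell lectin Klrg1 fell by 2.13 ± 0.16, Gzmk fell by 1.53 ± 0.08, Lef1 fell by 1.39 ± 0.15, the trefoil factor Tff1 fell by 1.37 ± 0.09 and Eomes, a transcription factor of memory and early exhausted cells, fell by 1.35 ± 0.10. Checkpoint receptors did not follow the rise seen over all T cells. Within this class Havcr2 fell by 0.42 and Pdcd1 fell by 0.26 (edgeR adjusted p = 0.0019 and 0.0352). Of the 18 inhibitory receptor and exhaustion genes, 9 fell and 1 rose (camera adjusted p = 0.380 with an estimated correlation). The class was named by markers that include Havcr2 and Pdcd1, and Havcr2 was among its leading genes. Its cells were thus picked on these genes, so the falls do not show a change within a state. The edgeR counts were 595 genes higher and 470 lower in this class. DESeq2 called 267 and 175, and without sgScr replicate 2 there were 254 and 230.

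In cycling-like cells, marked by mitotic genes, Ccl1 rose by 1.98 ± 0.22, Gzmc by 1.87 ± 0.14, Xcl1 by 1.75 ± 0.13, the signalling regulator Rgs2 by 1.66 ± 0.17 and Gzmf by 1.63 ± 0.37. Gzmk fell by 1.53 ± 0.08, Eomes fell by 1.12 ± 0.10, the surface receptor Cd7 fell by 0.97 ± 0.11, the chemokine receptor Cxcr3 fell by 0.94 ± 0.16 and the integrin Itgb7 fell by 0.89 ± 0.16. In all, 325 genes were higher and 255 lower. This count was 245 and 72 with DESeq2, 162 and 147 without sgScr replicate 2, 487 and 471 without sgArid1a replicate 1, 577 and 380 without sgArid1a replicate 2 and 656 and 517 with the replicate number as a block. In early-activated-like cells the growth factor gene Il2 rose by 2.46 ± 0.45, Ccl3 by 2.17 ± 0.15, Ccl4 by 2.03 ± 0.19, Ccl1 by 1.68 ± 0.27 and Isg15 by 1.29 ± 0.30, while Ebi3, Ramp1, Camk2n1, Tsc22d3 and Gzmk fell by 1.44, 1.40, 1.39, 1.39 and 1.36. The counts were 90 higher and 48 lower (53 and 14 with DESeq2, 217 and 130 with the block).

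In naive/central memory-like cells, which express Ccr7 and Lef1, the stress and activation genes Fos, Jun and Dusp1 rose by 1.44 ± 0.07, 0.99 ± 0.07 and 0.98 ± 0.10, S100a6 by 0.93 ± 0.10 and Rgs1 by 0.86 ± 0.11. The mTOR inhibitor Ddit4 fell by 0.91 ± 0.08, Tsc22d3 fell by 0.80 ± 0.08, Tmie fell by 0.69 ± 0.11, Dtx1 fell by 0.61 ± 0.10 and Pik3ip1 fell by 0.61 ± 0.07. Gzma and Ccl5, which are abundant in other classes, also rose in it, by 1.74 and 0.54, and RNA free in the droplets was not removed. The counts were 647 higher and 337 lower. They were 276 and 44 with DESeq2, 119 and 65 without sgScr replicate 1, 102 and 31 without sgScr replicate 2, 1065 and 801 without sgArid1a replicate 1 and 300 and 142 at the lower clustering resolution.

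Isg15 was among the 5 largest rises in 4 of the numbered clusters, cluster 5 being the exception. It rose by 2.35 ± 0.24 in cluster 10 (led by the killer cell lectins Klra7 and Klra6), by 1.52 ± 0.11 in cluster 8 (Ccr2, Ccl5 and Cxcr3), by 1.45 ± 0.14 in cluster 2 (Id3, Ms4a4c and Gbp2) and by 1.43 ± 0.14 in cluster 3 (Ccl5, Car2 and Cxcr3). In cluster 10 Gzmb (2.50 ± 0.33), Rtp4, Fos and Ifi27l2a also rose, and Pja2, Tsc22d3, Bbc3, Specc1l and St6gal1 fell. In cluster 8 the transmembrane protein Ifitm1 rose by 1.96 ± 0.45, Dapl1 by 1.57 ± 0.19, Rtp4 by 1.34 ± 0.11 and the heat shock gene Hspa1b by 1.28 ± 0.18, while Camk2n1, Ccr2, Pik3ap1, Rap2a and Eomes fell, with log2 changes of -1.02 ± 0.10 for Ccr2 and -0.82 ± 0.14 for Eomes. In cluster 2 Gzmb, Fos, Tgtp1 and Ccl4 rose, and Ddit4, Dido1, Tsc22d3, S100a6 and Txnip fell. In cluster 3 Fos, Dusp1, Hspa1b and Ifit3 rose, and Hid1, Zc3h4, Tcf20, Ddit4 and Slc20a1 fell. In cluster 5, whose cells had few UMIs and a median of 6.62% mitochondrial UMIs, Sf3b4, Ccl1, Ftsj3, Ccr6 and Xcl1 rose, and Pde2a, Sfi1, Scml4 and Tsc22d3 fell. Gzmb, Ccl4, Ccl1 and Xcl1 are abundant in other classes, and RNA free in the droplets was not removed. Their rises in clusters 10, 2 and 5 are thus not read as expression by those cells. In effector-like cells, which express Gzma, S1pr5 and Klrg1, Ifi27l2a (1.06 ± 0.22), Junb (0.94 ± 0.16), Gzma (0.76 ± 0.15), Ltb (0.73 ± 0.15) and Jund (0.67 ± 0.14) rose, and none of the 2 genes that fell met the rule for naming.

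Counts in these classes were small and depended on the samples and, for effector-like cells, on the clustering, where a resolution of 1.2 gave 101 higher and 45 lower. They were 159 higher and 62 lower in cluster 10, 108 and 37 in cluster 3, 83 and 60 in cluster 8, 94 and 28 in cluster 5, 50 and 8 in cluster 2 and 11 and 2 in effector-like cells. DESeq2 called 51 and 14, 55 and 6, 35 and 20, 33 and 3, 23 and 4 and 1 and 0 in the same order. Leaving out 1 sample at a time moved the totals from 65 to 388 in cluster 10, from 78 to 690 in cluster 3, from 81 to 488 in cluster 8, from 37 to 147 in cluster 5, from 31 to 198 in cluster 2 and from 9 to 33 in effector-like cells. Each total was lowest without an sgScr sample, and each was highest without an sgArid1a sample except in cluster 5.

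Across the 10 classes tested, the type I interferon-stimulated list was called as raised in 7, the interferon-gamma response list in 7, the heat shock and dissociation list in 10, the oxidative phosphorylation list in 10, the chemokine list in 8, the cytotoxic list in 6 and the T cell receptor-induced list in 5. The median log2 fold change of the type I list was highest in cluster 10 (0.98) and lowest in cluster 5 (-0.34), and that of the heat shock list lay between 0.34 and 0.58. G2/M genes were raised as a list in 3 classes and lowered in cycling-like cells (median -0.21), progenitor and memory genes were lowered in 4 classes and raised in cluster 8, and inhibitory receptors were raised in naive/central memory-like cells and lowered in 2 classes. Terminally exhausted-like cells, where inhibitory receptors were lowered, were themselves named by such genes. The naive/central memory-like class is among those raised for the cytotoxic, chemokine, T cell receptor-induced, G2/M and inhibitory receptor lists. Free RNA and doublets were not removed, so these rises are not read as expression by naive cells. The same limit holds for the cytotoxic and chemokine lists in the numbered clusters. No list was called in any class with an estimated correlation, a form of the test with little power at 4 samples. The smallest value was adjusted p = 0.0690 with an estimated correlation for the interferon and heat shock lists in cluster 3.

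**Figure D3:**
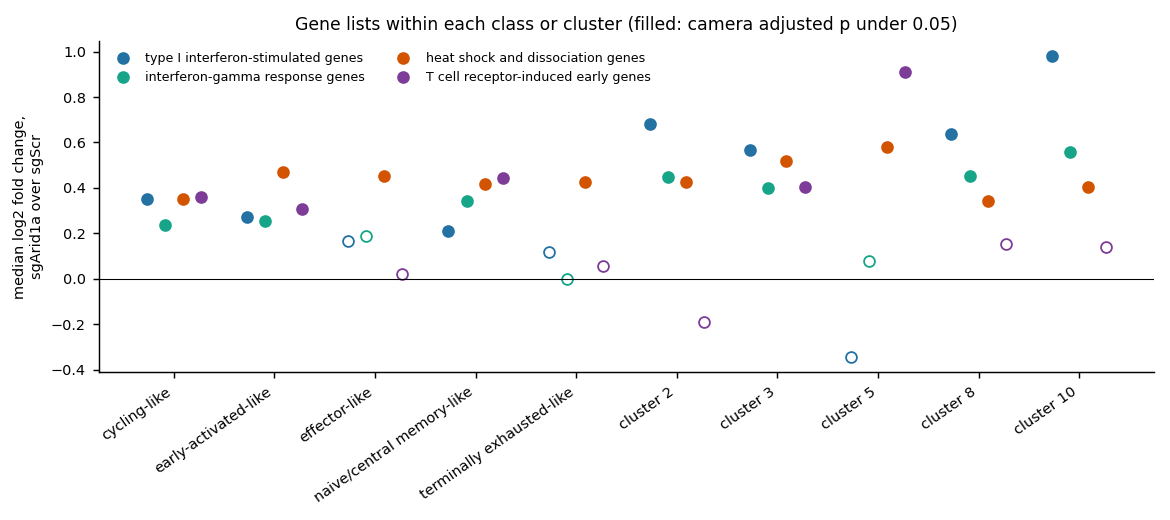
Median log2 fold change, sgArid1a over sgScr, of 4 gene lists within each of the 10 classes or clusters tested; filled circles were called by camera at the preset correlation and open circles were not, and none was called with an estimated correlation. The heat shock and dissociation list lies between 0.34 and 0.58 in all 10, and the type I interferon-stimulated list is highest in cluster 10 at 0.98.

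The group effect itself was compared between the classes with most cells, naive/central memory-like cells and cluster 8. In edgeR's interaction test 306 of 10551 genes differed, 94 with the higher change in cluster 8 and 212 with the lower. Isg15 and Ifi27l2a, an interferon-induced mitochondrial protein, rose more in cluster 8 (differences of 0.97 and 0.74), and Dapl1 rose there by 1.57 against -0.17 in naive/central memory-like cells. Il7r, the interleukin-7 receptor, fell by 0.38 in naive/central memory-like cells and rose by 0.53 in cluster 8. The fitted rises of Gzmb, Gzma and Ifng were larger in naive/central memory-like cells (differences of -1.72, -1.50 and -2.38). These transcripts are abundant in other classes and RNA free in the droplets was not estimated, so the values are not read as expression by naive cells. The count was 165 without sgScr replicate 1, 143 without sgScr replicate 2, 151 without sgArid1a replicate 1 and 81 without sgArid1a replicate 2.

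The mix of cell states was compared with a clustering that left out the 6975 genes called between groups or in the interferon lists. Naive/central memory-like cells took 54.3 ± 0.879% of the T cells in sgScr and 35.1 ± 6.71% in sgArid1a (mean ± SD, n = 2), a log2 ratio of -0.63 ± 0.20 (edgeR adjusted p = 0.0291). A cluster named cycling-like by its markers, of whose 6968 cells 2698 belonged to the cycling-like, 2862 to the terminally exhausted-like and 669 to the early-activated-like class, went from 11.7 ± 0.411% to 22.2 ± 1.90% (log2 0.93 ± 0.18, edgeR adjusted p = 0.00827), and early-activated-like cells from 0.503 ± 0.0995% to 0.930 ± 0.257% (log2 0.90 ± 0.30, edgeR adjusted p = 0.0291). A cluster led by Ccl5, Cxcr3 and Ccr2 stood at 20.01 and 25.91% and a cluster led by Klra7 and Klra6 at 12.2 and 15.3%, neither passing the test (edgeR adjusted p = 0.0866 and 0.170). A small cluster of cells with few UMIs fell from 1.28 to 0.524% (log2 -1.29 ± 0.34, edgeR adjusted p = 0.0182). Of the naive/central memory-like clusters, cluster 1 fell from 22.7 to 9.18% (log2 -1.31, edgeR adjusted p = 0.0160), while cluster 0 stood at 31.55 and 25.96% (edgeR adjusted p = 0.387). Of the 10621 cells of cluster 0, 8314 belonged to the naive/central memory-like class, and of the 5561 of cluster 1, 3860 did. They also held 1105 and 694 cells of cluster 2 of the clustering with all genes. The cluster led by Klra7 and Klra6 took 1742 cells of the naive/central memory-like class.

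The exact two-sided permutation test gave p = 0.333 for these 6 shares, the smallest value 2 against 2 samples allow. The calls for naive/central memory-like and early-activated-like cells were lost without either sgScr sample and without sgArid1a replicate 2 (adjusted p from 0.0522 to 0.169), and that for cycling-like cells without sgScr replicate 1 (0.0772) or 2 (0.0907). Clustering with all genes gave log2 ratios of -1.24 for naive/central memory-like cells and 1.73 for cycling-like cells (3.09 to 10.2% of T cells), but its clusters rest on genes that themselves differed between the groups. The clustering without called genes has the opposite limit. Genes that mark states were among those left out, which can shrink differences in shares. Its clusters were still named with all genes.

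**Figure D4:**
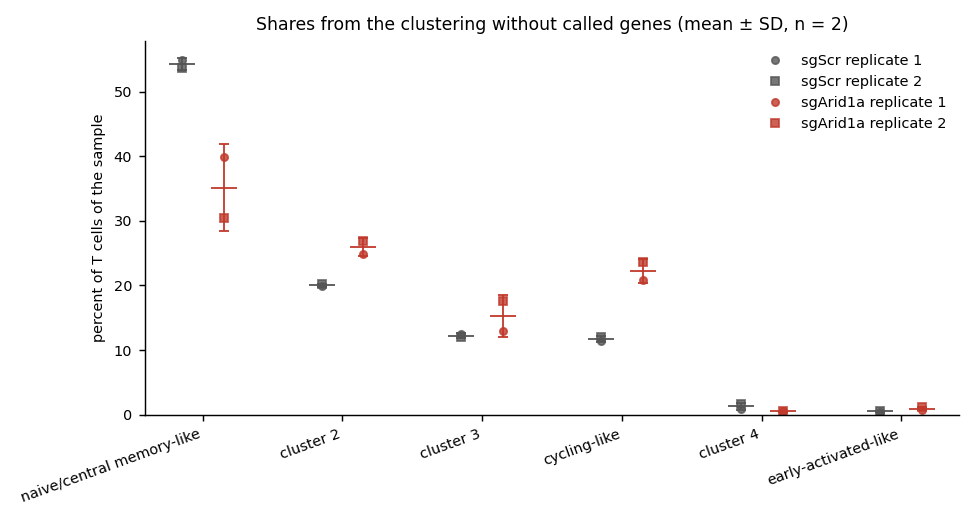
Percent of each sample's T cells in each class or cluster of the clustering without called genes; grey marks are sgScr, red marks sgArid1a, circles replicate 1 and squares replicate 2, and horizontal lines with bars give the mean ± SD of 2 samples. Naive/central memory-like cells lie at 54.3% in sgScr and 35.1% in sgArid1a on average, and the cluster named cycling-like, which also holds most cells of the terminally exhausted-like class, at 11.7% and 22.2%.

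Receptor usage was read from the variable segments in the 5-prime libraries; the receptor amplification libraries were not used here. A leading Trbv segment was found in 78.7 and 76.8% of the T cells in sgScr and in 67.6 and 79.4% in sgArid1a. The leading segment was Trbv19 in sgScr (10.3 and 10.7%) and Trbv13-1 in sgArid1a (14.3 and 13.3%). Of 21 segments tested, 14 differed in edgeR. Trbv20 rose from 2.59 ± 0.106% to 8.10 ± 0.444% (log2 1.64 ± 0.09), Trbv5 by 1.62 ± 0.33 from 0.167%, Trbv13-1 by 0.82 ± 0.07 and Trbv3 by 0.56 ± 0.07, while Trbv4 fell by 1.53 ± 0.18, Trbv15 fell by 0.65 ± 0.10, Trbv19 fell by 0.57 ± 0.07 and Trbv14 fell by 0.56 ± 0.10. Shannon diversity was 4.08 ± 0.00604 bits in sgScr and 3.99 ± 0.0162 bits in sgArid1a (mean ± SD, n = 2), a difference of -0.0817 bits (exact permutation p = 0.333); it was -0.0585 bits with segments at 1 UMI or more and -0.139 bits at 4 UMIs or more.

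The shift sat in the activated classes. In terminally exhausted-like cells Trbv13-1 led in 35.3 and 34.4% of the cells of the sgArid1a samples and Trbv20 in 28.8 and 27.8%, against 13.8 and 9.52% and 0.601 and 0.595% in the sgScr samples. There Trbv19 led in 25.2 and 24.4% and Trbv16 in 18.9 and 24.7%. In naive/central memory-like cells Trbv13-1 led in 6.86 and 7.49% of the sgScr and 7.86 and 5.99% of the sgArid1a cells. Of the cells with both a Trav and a Trbv segment, the pair Trav10 with Trbv13-1 took 254 of 2021 (12.6%, 95% Wilson interval 11.2 to 14.1%) and 387 of 4110 (9.42%, 8.56 to 10.3%) in sgArid1a, and 3 of 2244 (0.134%, 0.0455 to 0.392%) and 2 of 2031 (0.0985%, 0.0270 to 0.358%) in sgScr. Trav7-3 with Trbv20 took 45 and 112 cells in sgArid1a and 0 in both sgScr samples, which allows a share of up to 0.134% and 0.148%. Trav13-1 with Trbv13-1 was the leading pair in sgScr, with 63 and 48 cells against 12 and 20. Intervals and limits cover counting error only. Removing all cells led by Trbv13-1 or Trbv20 left 2568 genes higher and 2370 lower in the T cells, and 185 of the 550 and 159 of the 365 genes kept a change of at least 2-fold. These segments were frequent in the terminally exhausted-like cells of sgArid1a, so the removal also changed the mix of states. Cells without a leading segment stayed in. The drop is thus not read as the part carried by expanded clones.

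**Figure D5:**
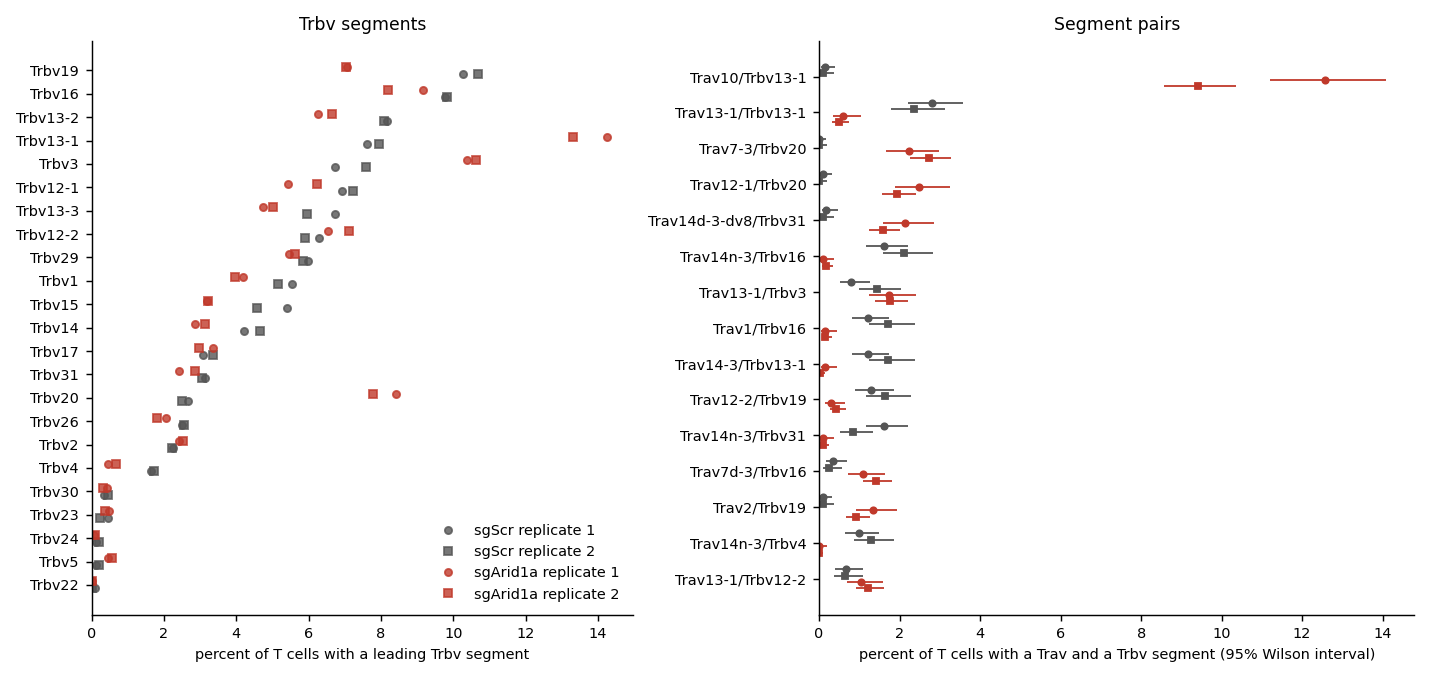
Left, percent of T cells with a leading Trbv segment that each segment takes; right, percent of T cells with both segments that each of 15 Trav and Trbv pairs takes, with 95% Wilson intervals. Grey marks are sgScr, red marks sgArid1a, circles replicate 1 and squares replicate 2; the pair Trav10 with Trbv13-1 lies at 12.6 and 9.42% in sgArid1a and under 0.392% in sgScr.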

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

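The interaction test below was planned before the data were examined, while the tests of explanations for the 3 patterns and the count of receptor pairs were chosen after the results were seen.

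The group effect differed between naive/central memory-like cells and cluster 8 for 306 genes in edgeR's interaction test. Values are the log2 fold change in cluster 8 minus that in naive/central memory-like cells. The named genes with the lower change in cluster 8 were Ccl1 (-2.97), Rpl39l (-2.50), Mki67 (-2.39), Ifng (-2.38), Ccl3 (-2.23), Gzmb (-1.72), Bhlhe40 (-1.22), Xcl1 (-1.17), Tnfrsf9 (-1.13), Pdcd1 (-0.86), Fos (-0.54), Prf1 (-0.46), Pgam1 (-0.40), Tpi1 (-0.36) and Ndufb7 (-0.23). Those with the higher change there were Il6ra (1.14), Ccr7 (1.03), Isg15 (0.97), Gbp6 (0.94), Dtx1 (0.81), Tsc22d3 (0.78), Pik3ip1 (0.68), Rtp4 (0.62), Klf3 (0.50) and Tcf7 (0.39). No gene list was tested on these differences, and free RNA of other classes was not removed from either class. The count was 165, 143, 151 and 81 without sgScr replicate 1, sgScr replicate 2, sgArid1a replicate 1 and sgArid1a replicate 2.

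Receptor segments were not part of the gene comparison and gave a signal of their own. The pair Trav10 with Trbv13-1 reached 12.6% of the cells with both segments in an sgArid1a library, against at most 0.134% in an sgScr library. Both libraries of a group shared such expanded pairs. Barcodes or reads crossing between the sgArid1a libraries are argued against by the shared barcodes, of which only 34.6 exceeded the number expected by chance, fewer than the 254 cells of this pair in the smaller count. The pair counts go with both libraries of a group being made from the same pool of cells or animals. Of the pairs tested, 0.429% differed between libraries of a group and 19.4 to 37.6% between libraries of different groups. The labels do not state such a pool. With it, the replicates may measure only the spread of library preparation and not that between mice. An expansion in few animals then cannot be told apart from an effect of the guide.

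Heat shock and dissociation genes, such as Dusp1, Fos and Hspd1, were raised as a list by camera at the preset correlation in 10 of 10 classes, and in 0 with an estimated correlation (smallest adjusted p = 0.0690 with an estimated correlation). A larger share of cells in the clusters of stressed or dying cells is argued against by their shares. The heat shock cluster went from 1.13 to 0.503% and the cluster with high mitochondrial share from 1.28 to 0.496% of T cells. Without them the median log2 fold change of the list was 0.44, against 0.35 over all T cells. That removal cannot decide, since taking out clusters rarer in sgArid1a tends to raise the value. Stressed cells spread through the other clusters stay open. Signalling through the T cell receptor, which induces some of the same genes, cannot be told apart, since its own list was called in 5 of the 10 classes. Different handling or dissociation of the tumours of each group could raise such genes in all 10 classes; nothing in the labels separates it from the group, so handling and a biological effect cannot be told apart.

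Type I interferon-stimulated genes, such as Isg15 and Rtp4, were higher in sgArid1a. A change in the mix of cell states as the whole cause is argued against, since the list was called as raised at the preset correlation in 7 of the 10 classes (0 with an estimated correlation, smallest adjusted p = 0.0690 with an estimated correlation) and single genes of it rose within classes, from 13 of 29 in cluster 8 to 3 of 25 in terminally exhausted-like, 1 of 16 in effector-like cells and 0 of 7 in cluster 5, while 0 fell in any of the 10 (1 fell in terminally exhausted-like cells adjusted over the list alone). A part for the mix stays open: the interferon-stimulated class went from 0.554 to 2.09% of T cells, and at the common cluster mix the median log2 change of the list went from 0.50 to 0.25, but these clusters were made with the same genes, so the values do not separate a change of mix from induction. Removing the cells led by Trbv13-1 or Trbv20 cannot decide on the expanded segments. The list's median log2 fold change was then 0.70, but the mix of states changed too, and cells without a leading segment stayed in. In cluster 8 the list's median was 0.64. There Trbv13-1 led in 5.30 and 5.31% of the sgArid1a cells, against 8.09 and 11.6% in sgScr. Trbv20 led in 3.94 and 2.71%, against 1.26 and 1.86%. These shares argue against such cells as the whole cause in cluster 8. Free RNA or doublets of macrophages, monocytes and dendritic cells stay open. Their summed markers rose by 107 CPM, against 408 CPM for the interferon list, in which Ifi27l2a alone went from 314 to 511 CPM. How much interferon-stimulated RNA such cells carry beside these markers is not known here, so the sums cannot decide. The remaining explanations cannot be told apart here. They are such free RNA or doublets, a part for the cells with the expanded segments, a response to interferon in the sgArid1a group, and a batch or pool difference between the groups.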

How the results depend on the processing

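The settings that leave out cells by receptor segments, doublet score or stressed clusters, the crossed block, the common cluster mix, the shorter ribosomal list and the leave-one-out fits of the interaction and of Trbv usage were chosen after seeing the data; the others were planned. At the common cluster mix, which has no test, 5 of the named called genes changed sign: Havcr2 (-0.39), Mki67 (-0.21), Pdcd1 (-0.0785), Slc16a3 (-0.0152) and Ifngr2 (0.00677); the clusters held equal there were made with all genes, which shrinks changes by construction. No called result changed direction under the other alternatives. Keeping doublets gave the same fit as the main setting, since 0 doublets were called, so that alternative adds no check. Of the 69 named genes, 64 were tested in all 23 tested alternatives for all T cells and 5 were not tested with at least 10 CPM; where tested, 68 stayed on their side of the threshold and Arid1a lost its call without sgScr replicate 2. The count for all T cells ranged from 4885 (genes with at least 10 CPM, where fewer were tested) to 7476.

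DESeq2 called 65 genes in cluster 10, 27 in cluster 2, 61 in cluster 3, 36 in cluster 5, 55 in cluster 8, 317 in cycling-like, 67 in early-activated-like, 1 in effector-like, 320 in naive/central memory-like and 442 in terminally exhausted-like cells; the cause was not tested. With the replicate number as a block, cycling-like cells gave 1173 and early-activated-like cells 347; the samples only share a number, and a crossed pairing gave 7432 genes in all T cells against 7055 with the block. Other clustering resolutions gave 146 in effector-like cells (resolution 1.2) and 442 in naive/central memory-like cells (resolution 0.5); the cause was not tested. With an estimated correlation, a form of the test with little power at 4 samples, 0 gene lists were called. The Shannon difference was -0.0585 bits at 1 UMI or more and -0.139 bits at 4 UMIs or more. For gene lists at the preset correlation, 314 results of the alternatives stayed on their side of the threshold, 24 passed it and 7 lost it. The ribosomal protein genes lost the camera call without sgScr replicate 1 (adjusted p = 0.268), sgArid1a replicate 2 (0.147), cycling-like cells (0.0872) or Trbv13-1 and Trbv20 cells (0.163), the natural killer cell markers without sgArid1a replicate 1 (0.110), and the interferon and STING signalling components without cycling-like cells (0.275) or Trbv13-1 and Trbv20 cells (0.246).

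Leaving out each sample in turn, with the lone sample of a group assumed to vary like the other group, gave 5170 to 7476 genes in all T cells, 65 to 388 in cluster 10, 31 to 198 in cluster 2, 78 to 690 in cluster 3, 37 to 147 in cluster 5, 81 to 488 in cluster 8, 309 to 958 in cycling-like, 141 to 164 in early-activated-like, 9 to 33 in effector-like, 133 to 1866 in naive/central memory-like and 484 to 1387 in terminally exhausted-like cells, and 81 to 165 for the interaction. Gene lists ranged from 15 to 19, Trbv segments from 12 to 15 and the Shannon difference from -0.0931 to -0.0702 bits. Log2 ratios of shares ranged from -0.84 to -0.44 for naive/central memory-like, 0.84 to 1.01 for cycling-like and 0.58 to 1.15 for early-activated-like cells. Thinning all sums to the smallest total left 6675 genes called in all T cells.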
